A study of Mus musculus with 4 samples.

How the data were processed

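Nuclear RNA of sorted spinal cord nuclei was measured by droplet-based single-nucleus RNA sequencing (10x Genomics 3' v3) in 4 libraries, 2 from uninjured and 2 from injured female mice. Group, replicate number, segment range and genotype were taken from the labels. Uninjured tissue spanned segments C1 to C8 and injured tissue C3 to C8, so the segment range and the injury cannot be told apart in any comparison. Nothing says whether the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

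Each deposited matrix held whole-number counts of unique molecular identifiers (UMIs) per gene and nucleus for 32285 gene symbols. Per the submitters' processing notes, Cell Ranger, Seurat 5.0.0 and the mm10 build were used. The Cell Ranger version and the use of strand in counting are not given in the sources used here. The names of the deposited matrices mention SoupX, a tool that subtracts counts attributed to RNA free in the suspension, and its version and settings are not given in the sources used here. Between 53.0% and 60.1% of the stored entries of each matrix held a 0. A sparse matrix normally stores no 0, so these entries were read as genes detected in a nucleus before the subtraction and emptied by it. This reading rests on the files alone, and not every original detection need be stored. On it, stored entries include detections of RNA free in the suspension. All 13 mitochondrially encoded genes had 0 counts in every library although 519 to 5356 stored entries named them, so the mitochondrial filter below removed no nucleus.

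The matrices held 569, 2399, 601 and 432 nuclei (uninjured 1, uninjured 2, injured 1, injured 2). Nuclei with fewer than 500 genes with a count (6, 324, 38 and 39) or with 5% or more mitochondrial counts (0) were left out. Scrublet, run per library through scanpy 1.11.5, called 3, 4, 12 and 4 nuclei doublets, 0.640% of those over the gene minimum, and these were left out. These calls and the borders of clusters vary with numerical precision, so both were run in a fixed setting on 1 thread. The remaining 3571 nuclei were log-normalized and integrated over the libraries with canonical correlation analysis in Seurat 5.3.0 (2000 variable genes, 30 dimensions, resolution 0.5), giving 18 clusters. Cell type markers were fixed before the data were examined, and the scoring rule was set afterwards. A marker counted for a cluster at 4-fold over the other nuclei with a stored entry in at least 5% of its nuclei. At least 3 such markers were needed for an inhibitory, cholinergic or non-neuronal name. A neuron call needed 3 pan-neuronal markers at 100 CPM (counts scaled to a common library total). Other neuron clusters were named glutamatergic neuron-like by any Slc17a6 count, 3 V2a-lineage genes stored in at least 5% of nuclei at any fold, and a minimum depth relative to their libraries. Shallow non-neuronal clusters kept a name only with a marker of that class among their leading genes. The 8 clusters numbered 0, 1, 4, 6, 8, 9, 10 and 13 were named glutamatergic neuron-like, and together they held 2163 nuclei. Cluster 7, with neuronal markers but 0 counts of Slc17a6 and 0.332 of the median counts of its libraries, stayed unnamed. Clusters that the rule left unnamed are described by their leading genes.

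Counts were summed over the glutamatergic neuron-like nuclei of each library, since nuclei are not replicates. The injured libraries were compared with the uninjured libraries by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05). The same test was run within each glutamatergic cluster with at least 20 nuclei in every library. Whether the injury difference of a cluster departed from that of the other glutamatergic nuclei was tested as an interaction with library as a block. In all, 28 gene lists fixed before the data were examined were tested on log2 CPM by camera with an inter-gene correlation of 0.01 (limma 3.58.1), with camera at an estimated correlation and fry beside it. Members of each list were also adjusted over the list alone. Shares of nuclei have exact (Clopper-Pearson) 95% intervals, and groups of libraries were compared by exact two-sided permutation tests, for which 2 libraries against 2 allow no p below 0.333. For shares of nuclei with a count, nuclei were thinned to 3800 counts, the 10th percentile of depth rounded down, and shallower nuclei were left out. Intervals and floors cover counting error only. A fold against a group at 0 is a lower bound against 3 counts over that group.

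Named genes follow a rule fixed in advance: the 12 largest called rises and falls with a mean log2 CPM of at least 4, or, with fewer than 5 calls in a direction, the 8 genes with the smallest p there, excluding predicted-gene symbols; up to 4 members of each list by smallest p; Sun1 as a check of the sort; up to 3 genes per direction and cluster past the threshold; and the 8 genes of the share test. Some genes that meet the rule are not reported here, and no others take their place. Genes outside the rule are said to have been chosen after their values were seen. Coordinates are those of GENCODE M21 (GRCm38, the assembly behind mm10), matched by symbol, and 31432 of the 32285 symbols had 1 annotated gene.

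The alternatives fixed in advance were DESeq2 1.42.0, RLE scaling, no low-count filter, the replicate number as a block, each library left out in turn, nuclei of every class, doublets kept, equal numbers of nuclei, limma-trend on mean log values, a threshold of 0.1 and clustering at resolution 1.0. Others were added after the data were seen: tests restricted to genes that kept a count in at least 25% or 50% of their stored entries in every library, the unnamed neurons added, the doublet calls of uninjured library 1 kept in, these kept in with another kernel of the linear algebra library, camera at an estimated correlation with each library left out, and tests of stored entries in place of counts. For the last, nuclei were matched across libraries on cluster and on the number of stored genes (2 bins per doubling), which left 246 glutamatergic nuclei per library. Tests of stored entries within and between clusters, and stored shares of single clusters, used all nuclei of the clusters without this matching. Over all glutamatergic nuclei, median stored genes were 5619.5 and 5283 in uninjured and 4300 and 4798 in injured libraries. Several forms of this matching were tried, and the one kept averages over the nuclei of each bin, with 10 random draws beside it. Shares of the 8 injury genes in matched nuclei are those of the first draw. Matched glutamatergic nuclei had median stored genes of 5103.5, 5052.5, 4916.5 and 5137.25, but their counts were not matched. Detection approaches its ceiling for abundant genes, so log2 differences of detection understate those of expression. Where the interaction was set against stored entries, genes stored in 95% or more of nuclei, in the cluster or the other glutamatergic nuclei of any library, were left out. Genes lying antisense to another gene were those with at least 50% of their length opposite a gene stored in at least 50% of nuclei, and their counts are uncertain because the use of strand is not given.

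Some of the tests were tried on simulated data drawn from the libraries' own means and sizes with 200 changed genes. Their own dispersions were used except for the interaction test. For the glutamatergic comparison edgeR recovered 17% of 4-fold and 31% of 8-fold changes over 11092 genes, and 97% and 100% over the 3440 genes that kept a count in at least 50% of stored entries. DESeq2 recovered 44.8% and 58.2% over 9948 genes and also called 76 unchanged genes, against 5 for edgeR. These simulations drew each gene around 1 mean and did not model genes emptied in a whole library. In edgeR 4.65% of the unchanged simulated genes had an unadjusted p under 0.05, against 219 of 11097 genes in the data. The recovery given is that of the simulated counts and may not hold for these data. The interaction test, run for cluster 0 over 3293 genes, recovered 66.7% and 92.9%. That simulation gave every gene the same fixed dispersion and used only genes that kept a count in at least 50% of stored entries. Its recovery and error rate therefore do not carry over to the interaction calls given below. The tests within clusters, the interaction in other clusters, fry and the permutation tests were not simulated. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.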

Results

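The series profiled nuclei of the V2a lineage, excitatory spinal interneurons, from the cervical cord of uninjured mice and of mice 5 days after hemisection at C2. In these mice Cre recombinase of this lineage switches on Sun1-sfGFP, a fluorescent protein of the nuclear envelope, and fluorescent nuclei were sorted. The 4 libraries held 7128996 and 13496025 total counts in the uninjured group and 3982267 and 2901680 in the injured group. Median counts per deposited nucleus were 10207 and 3512 in uninjured and 4948 and 5985.5 in injured libraries. After filtering, 560 and 2071 uninjured and 551 and 389 injured nuclei were analysed.

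The first question was which cells the sort had collected. Glutamatergic neuron-like nuclei made up 91.4% (95% interval 88.8 to 93.6) and 42.3% (40.2 to 44.5) of the uninjured libraries and 79.3% (75.7 to 82.6) and 86.9% (83.1 to 90.1) of the injured libraries. Uninjured library 2 stood apart, with 31.7% oligodendrocyte-like and 5.26% astrocyte-like nuclei, whereas oligodendrocyte-like nuclei were 2.32%, 1.45% and 1.03% of the other libraries. Inhibitory neuron-like nuclei, led by Cdh3, Pax2, Gad1 and Pax8, were 0.536% and 5.60% of the uninjured libraries and 0 of 551 and 0 of 389 injured nuclei, which in this clustering allows shares of up to 0.544% and 0.771%. That 0 depends on cluster borders: under another numerical kernel, chosen after the data were seen, the inhibitory cluster held 3.81% and 3.60% of the injured nuclei, 21 and 14. These 21 and 14 nuclei had a stored entry of Gad1 or Pax2 in 0 cases and of Slc17a6 in 76.2% and 64.3%, and all but 1 of them lay in the glutamatergic cluster 4 here. Of the uninjured library 2 nuclei that moved, 57 lay in the glutamatergic cluster 1 here, with Gad1 stored in 28.1% and Pax2 in 40.4%, and inhibitory neurons within cluster 1 of that library are not excluded. At resolution 1.0, a glutamatergic neuron-like cluster with Gad2 among its leading genes held 43 and 153 uninjured and 21 and 18 injured nuclei. Inhibitory neurons among the glutamatergic nuclei of the other libraries are therefore not excluded either. Oligodendrocyte precursor-like nuclei averaged 0.838% ± 0.932 (SD, n = 2) in uninjured and 0.129% ± 0.182 in injured libraries, pericyte or fibroblast-like nuclei 0.403% ± 0.318 and 0.749% ± 0.032, and neurons left unnamed 8.38% ± 5.29 and 11.5% ± 0.964, in the same order. Among the unnamed neurons, cluster 7 held 2.71% ± 1.72 of uninjured and 11.2% ± 0.889 of injured nuclei, and cluster 5, led by Nmu, Ebf2, Lmx1b and Calb1, 4.68% ± 5.61 and 0.310% ± 0.075. With 2 libraries against 2 no exact permutation p can pass, so whether the classes differ is left open: it was at the smallest value possible for inhibitory, oligodendrocyte-like and pericyte or fibroblast-like nuclei, 0.667 for unnamed neurons, precursors and astrocyte-like nuclei, and 1.0 for glutamatergic and unnamed non-neuronal nuclei. Sorting purity and segment range can set all of these shares.

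**Figure D1:**
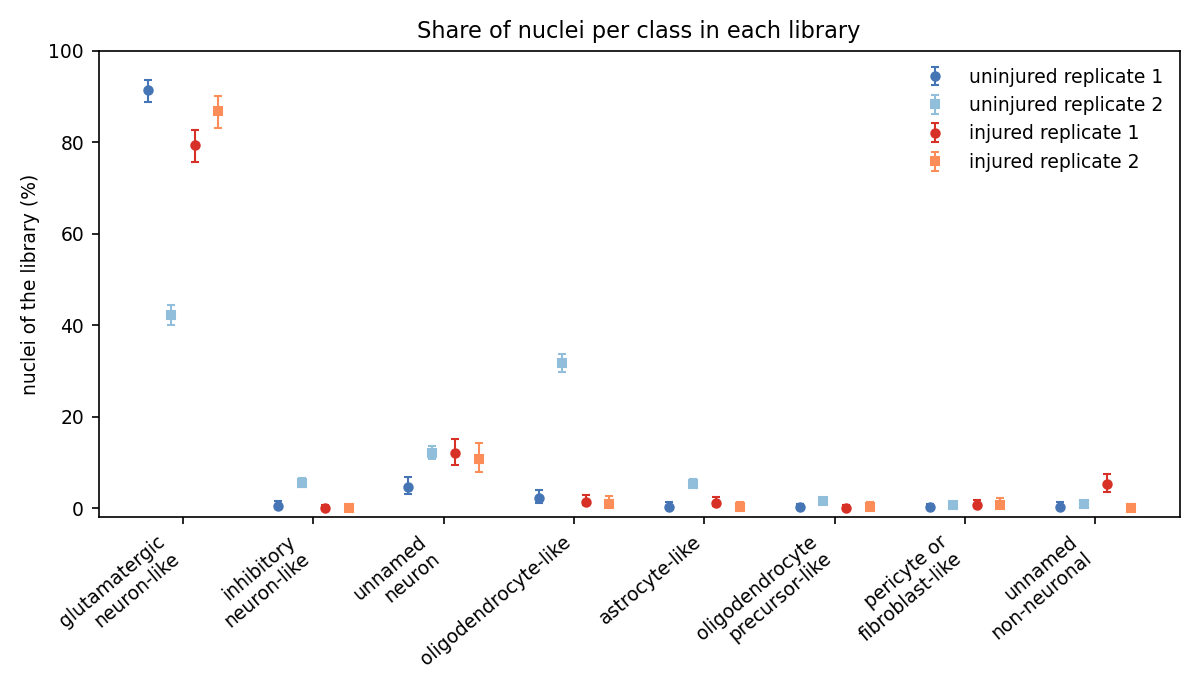
Share of analysed nuclei (y axis, percent) in each class (x axis) for the 2 uninjured and 2 injured libraries, each point 1 library with its exact 95% interval. Glutamatergic neuron-like nuclei range from 42.3% to 91.4% of a library, and uninjured replicate 2 holds 31.7% oligodendrocyte-like nuclei.

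The gene of the label was detected in both groups. Sun1, whose tagged form is the label, had a stored entry in 56.1% to 62.7% of glutamatergic neuron-like nuclei, and its level was 28.7 ± 7.28 CPM in uninjured and 52.2 ± 3.23 CPM in injured libraries. It was named as a check of the sort, but counts by gene symbol do not tell its tagged form from the untagged one. Detection of Sun1 therefore cannot show that the label was present. Stored zeros are read here as detections emptied by the ambient subtraction, a reading that rests on the files alone. Slc17a6, the vesicular glutamate transporter of these neurons, chosen here after its values were seen, had a stored entry in 89.5%, 73.4%, 83.8% and 84.3% of the glutamatergic nuclei (uninjured 1, uninjured 2, injured 1, injured 2), yet it kept only 36, 8, 0 and 135 counts. Of 10428 genes stored in over 10% of glutamatergic nuclei of every library, 2294 had 0 counts in some libraries and 1007 in all 4. On this reading a gene's counts can differ between libraries because of the subtraction, so the share of matched nuclei with a stored entry, averaged over the nuclei of each bin of the matching, is given beside the counts of the genes with the smallest p.

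The second question was which genes differed in glutamatergic neurons 5 days after hemisection. These nuclei numbered 512 and 876 in uninjured and 437 and 338 in injured libraries, with 6870358, 9446932, 3702899 and 2732414 summed counts. Cluster 0 was the largest of their clusters in both injured libraries (167 and 109 nuclei, against 79 and 69 in cluster 1), whereas cluster 1 was the largest in uninjured library 2 (327 nuclei, against 256) and about equal to cluster 0 in uninjured library 1 (139 and 140). No gene passed in edgeR, and the genes named here have the smallest p in each direction and did not pass (adjusted p 1.00 in edgeR for each). Levels are mean CPM ± SD over 2 libraries per group. Erbb4, a neuregulin receptor tyrosine kinase (chromosome 1, 68032186 to 69108059, minus strand), stood at 519 ± 10.2 in uninjured and at 192 and 228 in the 2 injured libraries, a log2 fold change of −1.33 (SE 0.17), and its detection in matched nuclei was 42.6% and 31.4%. Fgf1, a fibroblast growth factor (chromosome 18, 38838673 to 38929472, minus strand, within Arhgap26 on the opposite strand), stood at 218 ± 32.2 and 93.9 ± 2.23, with detection of 81.5% and 65.3%. Cd163l1, a scavenger receptor family member (chromosome 7, 140218267 to 140231145, plus strand), stood at 48.8 ± 19.9 and 5.42 ± 4.23, with detection of 50.9% and 6.33%. Kcnc2, a Kv3 potassium channel subunit, stood at 352 ± 22.7 and 221 ± 3.18, with detection of 64.97% and 56.8%. Log2 fold changes were −0.63 (SE 0.17) for Kansl1l, with detection of 93.8% and 84.8%, and −0.86 (SE 0.22) for Zdhhc2, a palmitoyltransferase that lies opposite Cnot7, with 68.8% and 55.6%. Tbce, a tubulin folding cofactor that lies opposite B3galnt2, had −1.11 (SE 0.26), but its detection was 74.9% and 70.4%.

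Among genes with higher levels after injury, Thsd4, which encodes a secreted thrombospondin-repeat protein (chromosome 9, 59966931 to 60522046, minus strand), stood at 105 ± 12.1 CPM in uninjured and 192 ± 23.9 CPM in injured libraries, a log2 fold change of 0.86 (SE 0.19), with detection in matched nuclei of 54.6% and 70.3%. Plce1, a phospholipase C, stood at 16.6 ± 4.31 and 49.4 ± 3.09 CPM, with detection of 20.9% and 28.3%. Cntn2, an axonal adhesion protein, stood at 3.07 ± 2.25 and 28.7 ± 3.78 CPM, but its detection was 58.6% and 62.0%. Dazap1, an RNA-binding protein (log2 fold change 2.89), and Nisch (3.12) likewise had detection that barely differed, 55.2% and 57.8% for Dazap1 and 82.8% and 80.5% for Nisch. Sbf1, Pnn and Leng9 had 0 counts in both uninjured libraries and were at least 231-fold, 208-fold and 198-fold higher in the injured libraries. Their detection in matched uninjured and injured nuclei was 46.0% and 58.7% for Sbf1, but 77.2% and 74.8% for Pnn and 67.9% and 58.4% for Leng9, which lies opposite Leng8, against the direction of the counts.

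**Figure D2:**
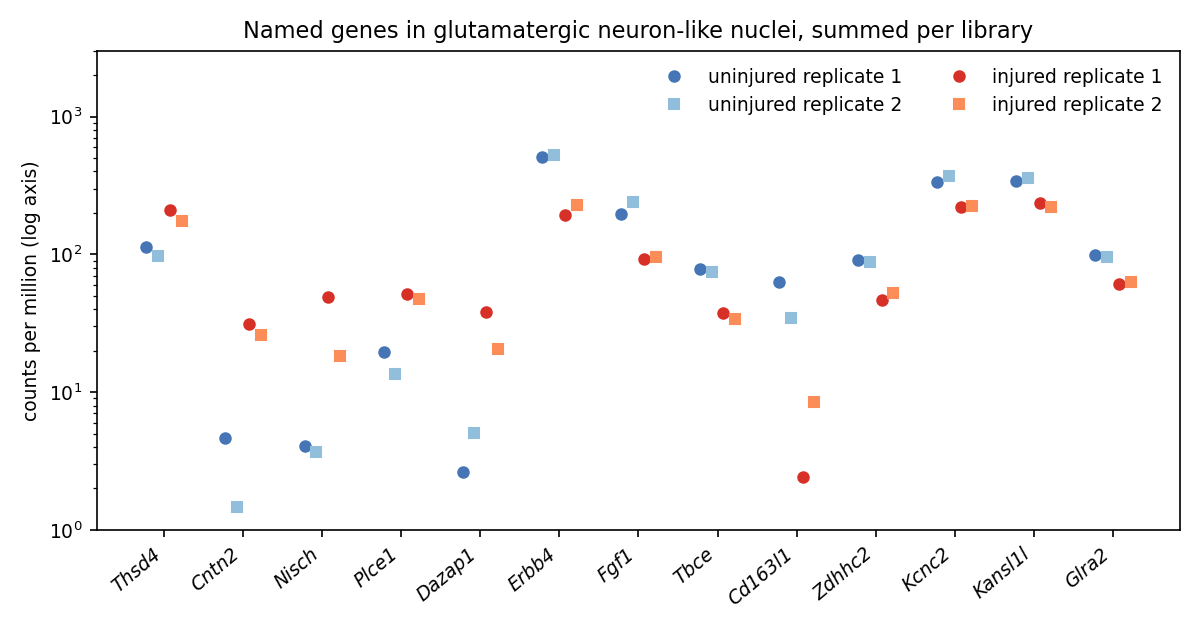
CPM (y axis, log scale) of 13 named genes (x axis) in counts summed over glutamatergic neuron-like nuclei, each point 1 library. Erbb4 stands at 512 and 526 in uninjured and 192 and 228 in injured libraries, and no gene passed the adjusted test.

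Over 11097 genes edgeR called 0, with 219 at an unadjusted p under 0.05. RLE scaling called 0 (218 genes at an unadjusted p under 0.05), limma-trend 0 (461), and DESeq2 11: Erbb4 (adjusted p 8.36e-08 in DESeq2) and Fgf1 (0.0394) lower, and Sbf1, Pnn, Leng9, Sv2a, Sirt2, Taf7, Rnaseh1, Mrps28 and Srsf1 higher, the last 5 chosen after their values were seen. The 9 higher genes had at most 3 counts over both uninjured libraries. Restricting the edgeR test to genes that kept a count in at least 50% of stored entries, a choice made after the data were seen, called Cd163l1 (adjusted p 9.32e-07 in edgeR), Fgf1 (0.0170) and Galntl6, a glycosyltransferase family member chosen after its values were seen (0.0323), lower and Thsd4 (0.0390) higher among 7 of 3440 genes. Without uninjured library 1 edgeR called 359 genes, 348 higher and 11 lower in the injured libraries, and 248 of these had 0 counts in the uninjured library that remained.

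Genes of axon injury and growth were the first of the lists examined. All 7 testable regeneration-associated genes had positive log2 fold changes (median 0.78). Basp1, a growth cone protein, stood at 1.32 ± 1.87 CPM in uninjured and 32.1 ± 31.2 CPM in injured libraries, with detection in matched nuclei of 75.6% and 75.2%. Flrt3, an adhesion protein that lies opposite Macrod2, had a log2 fold change of 0.50 with detection of 65.9% and 62.3%, Sox11, a growth-associated transcription factor, 0.78 with 22.99% and 21.8%, and Gap43, the growth-associated protein, 0.31 (SE 0.39) with 73.98% and 72.9%. Of the immediate early genes, Nr4a3 and Nr4a1 could be tested and both were positive (median 1.98), but Nr4a1 was negative in stored entries of matched nuclei (−0.17). The p53 and apoptosis list had 4 of 6 members positive. All 3 interferon and antigen presentation genes tested, Irf9 and Stat2 among them, were positive (median 0.90), and the 6 gp130 and JAK-STAT genes had 3 positive, among them Tyk2, and 3 negative. The axon growth cytoskeleton list had 5 positive and 6 negative members, the neurotrophic factors and receptors 6 and 5, and the 12 cholesterol synthesis genes 9 and 3, with Lss at a log2 fold change of 0.77. No member of these lists passed over all genes tested or adjusted over the list alone. In camera the regeneration-associated genes had p 0.0157 (adjusted p 0.123), the immediate early genes 0.0442 (0.158) and cholesterol synthesis 0.0246 (0.123), against adjusted p 0.924 with an estimated correlation for each. In stored entries of matched nuclei 9 of 13 regeneration-associated genes were positive (adjusted p 0.286 in camera) and 4 of 15 cholesterol synthesis genes (0.822). Camera called the cholesterol synthesis list without uninjured library 1 (adjusted p 0.00451, estimated-correlation adjusted p 0.708) and without injured library 1 (0.0406, estimated-correlation adjusted p 0.946). It did not pass without injured library 2 (adjusted p 0.551 in camera) and took the opposite direction without uninjured library 2 (0.838).

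Receptor and channel lists had mostly negative members in counts, and none of these lists passed. Without uninjured library 2 the direction in camera turned positive for the AMPA, NMDA and kainate, the metabotropic glutamate, the potassium and HCN and the calcium channel lists, and without injured library 2 for the first and the last of these. The GABA-A and glycine, serotonin and monoamine and sodium channel lists stayed negative whichever library was left out. Of the 16 GABA-A and glycine receptor genes, which encode the receptors of fast inhibition and gephyrin, 14 had negative and 2 positive log2 fold changes (median −0.26), and none passed over all genes tested or adjusted over the list alone. Glra2, a glycine receptor subunit, stood at 97.1 ± 1.48 CPM in uninjured and 61.5 ± 1.48 CPM in injured libraries, a log2 fold change of −0.67 (SE 0.20), with detection of 49.1% and 38.8%. The GABA-A receptor subunit genes Gabrb1 and Gabrg3 had log2 fold changes of −0.36 and −0.58. The list missed the threshold in camera (p 0.00300, adjusted p 0.0749), and had adjusted p 0.924 with an estimated correlation and 0.551 in fry. In stored entries of matched nuclei the list was also negative in camera and did not pass (adjusted p 0.675, estimated-correlation p 0.437), with 9 of 16 members negative. Htr2c, the serotonin 2C receptor, stood at 1175 ± 29.9 and 825 ± 41.8 CPM, with detection of 88.5% and 85.4%, and its list of serotonin and monoamine receptors had 6 of 11 members negative in counts and 4 of 12 positive in stored entries. Negative members were 5 of 6 voltage-gated sodium channel genes (median −0.38, Scn3a at −0.45, camera p 0.0238), 13 of 21 potassium and HCN channel genes (Kcnc2 at −0.69, camera p 0.0405) and 9 of 14 calcium channel genes. Of the AMPA, NMDA and kainate receptor genes 10 of 15 were negative, with Gria2 at −0.31, and of the metabotropic glutamate receptor genes 4 of 6, with Grm8 at −0.60. Positive members in stored entries of matched nuclei, where 46.0% of 9363 genes stored in under 50% of nuclei and outside the antisense set described below were negative, were 6 of 9 sodium, 12 of 22 potassium and HCN and 11 of 15 calcium channel genes, 12 of 17 AMPA, NMDA and kainate receptor genes and 5 of 6 metabotropic glutamate receptor genes. None of these lists passed there, and the potassium and HCN list was negative in camera (adjusted p 0.909). The share of 46.0% leaves out genes stored in 50% or more of nuclei, and list members can be stored that often. It is therefore no like background for these lists, and no such share is given for the tallies in counts.

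Synaptic adhesion and vesicle genes were mostly negative in counts and mostly positive in stored entries. Of 20 synaptic adhesion genes 17 were negative (median −0.22, camera p 0.0241, adjusted p 0.123), with Lrrtm1, which lies opposite Ctnna2, at −1.57 and Nrxn2, a presynaptic neurexin, at 0.72, and of 18 synaptic vesicle and release genes 14 were negative, with Rims2 at −0.26. In stored entries of matched nuclei 17 of 22 synaptic adhesion genes were positive (median 0.04) and 20 of 22 synaptic vesicle genes (camera adjusted p 0.0439, estimated-correlation p 0.168). Of 27 axon guidance genes 18 were negative. Without uninjured library 2 the direction in camera turned positive for the synaptic vesicle (adjusted p 0.634) and axon guidance lists (0.899), and synaptic adhesion stayed negative (0.899); axon guidance was also positive without injured library 2 (0.873). Epha3, an ephrin receptor, stood at 86.05 ± 10.5 CPM in uninjured and 52.65 ± 4.59 CPM in injured libraries, with detection of 39.7% and 30.8%, and Sema6a, a transmembrane semaphorin, at 91.9 ± 28.0 and 149.9 ± 10.0 CPM, with 61.7% and 65.8%. The perineuronal net and matrix list had 4 of 7 members negative, with Has1, a hyaluronan synthase, at 46.0 ± 13.6 and 25.4 ± 6.52 CPM, with detection of 48.4% and 27.8%. The factors reported to mark projection (Z-type) spinal neurons had 5 of 7 members negative (median −0.31, camera p 0.0687), with Zfhx3 at −0.31, and those of local (N-type) neurons 2 of 6. The rostral Hox genes, which set segmental identity, had 2 of 7 members negative and the caudal Hox genes 0 of 3, with Hoxb6 at 1.79 (SE 0.80). For the rostral Hox list (median 0.08) and the gp130 list (median −0.01) the direction in camera was opposite to the sign of the median. Single members of the heat shock (Hspa4l, −0.41) and oxidative phosphorylation (Ndufs1, −0.34) lists could be tested, and no member of the stress response, neuropeptide or mitochondrially encoded lists. Camera called 0 of the 25 testable lists, with 7 at an unadjusted p under 0.05, camera with an estimated correlation called 0 (0) and fry 0 (0), and no member of these or the receptor and channel lists passed over all genes tested or adjusted over the list alone.

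The third question was how many glutamatergic nuclei carried transcripts of 8 injury-response genes. After thinning, Atf3, a transcription factor induced by axon injury, its partner Jun and Sprr1a, a growth-associated gene of injured neurons, had a count in 0 nuclei of every library. This does not limit the share of nuclei with the transcript, since a gene with stored entries can be at 0 counts: Jun had 0 counts without thinning as well, yet was stored in 11.5%, 10.4%, 7.55% and 16.0% of the same nuclei (uninjured 1, uninjured 2, injured 1, injured 2). Gap43 had a count in 15.1% ± 2.95 of uninjured and 19.99% ± 4.48 of injured nuclei, Sox11 in 5.02% ± 3.09 and 5.30% ± 1.32, and Ecel1, an injury-induced endopeptidase, in 0.887% ± 1.25 and 2.05% ± 1.95. Stat3, a transcription factor of cytokine signalling, had a count in 11.1% and 1.18% of uninjured and 16.2% and 12.1% of injured nuclei. Gal, a neuropeptide gene, was at 0% in uninjured and 0.336% ± 0.475 in injured libraries. Without thinning, Gap43 was at 22.6% and 23.6%, Sox11 at 7.21% and 7.98%, Stat3 at 12.6% and 19.7% and Ecel1 at 1.26% and 1.85%. Thinning left out 26, 30, 116 and 40 shallower nuclei, and exact permutation p was at the smallest value possible for Stat3 and 0.667 or 1.0 for the others. The 903 non-neuronal nuclei were not thinned and had a median of 1840 counts, against 6342 to 10830 in glutamatergic nuclei. Their shares with a count were 0.221% for Gap43, 6.76% for Stat3 and 0% for the other genes. Of these nuclei 828 came from uninjured library 2. By library their Stat3 share was 36.8%, 5.43%, 17.0% and 11.1% (19, 828, 47 and 9 nuclei). Whether these cells express Stat3 themselves is not known, so they set no background for Stat3 in glutamatergic nuclei.

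Stored entries, read here as detections before the subtraction, gave a different view of the same genes, in nuclei matched on the number of stored genes. The shares given here are those of 1 random draw of the matched nuclei, and so differ from the averages given for the lists. Counts per matched nucleus still differed, with medians of 9281.75 and 8810 in uninjured and 8209.25 and 7744.5 in injured libraries. Ecel1 was stored in 7.32% and 12.2% of 246 matched uninjured nuclei and in 17.1% and 13.0% of injured nuclei. Atf3 was stored in 0.813% and 0.407% of uninjured and in 1.22% and 2.03% of injured nuclei. Jun was stored in 8.13% and 10.6% of the uninjured and in 9.35% and 17.5% of the injured nuclei. Gap43 (71.3% ± 3.16 and 71.5% ± 4.02), Stat3 (47.8% ± 2.01 and 47.6% ± 2.87) and Sox11 (20.9% ± 1.44 and 21.5% ± 1.73) differed by less than the intervals of single libraries, and their direction varied with the draw: the injured libraries were higher in 2 of 10 draws for Gap43, 3 for Sox11 and 2 for Stat3. Gal (1.02% and 1.83%) and Sprr1a (0% and 0.407%) were rare. Exact permutation p was at the smallest value possible for Atf3 and Ecel1, and larger for the others. Both injured libraries lay above both uninjured ones in 10 of 10 draws for Ecel1, 8 for Atf3 and 1 for Jun. In non-neuronal nuclei, which were shallower and may express some of these genes themselves, stored shares were 0.332% for Ecel1, 0.111% for Atf3 and 5.54% for Jun. They were 4.43% for Gap43, 0.775% for Sox11 and 21.8% for Stat3.

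**Figure D3:**
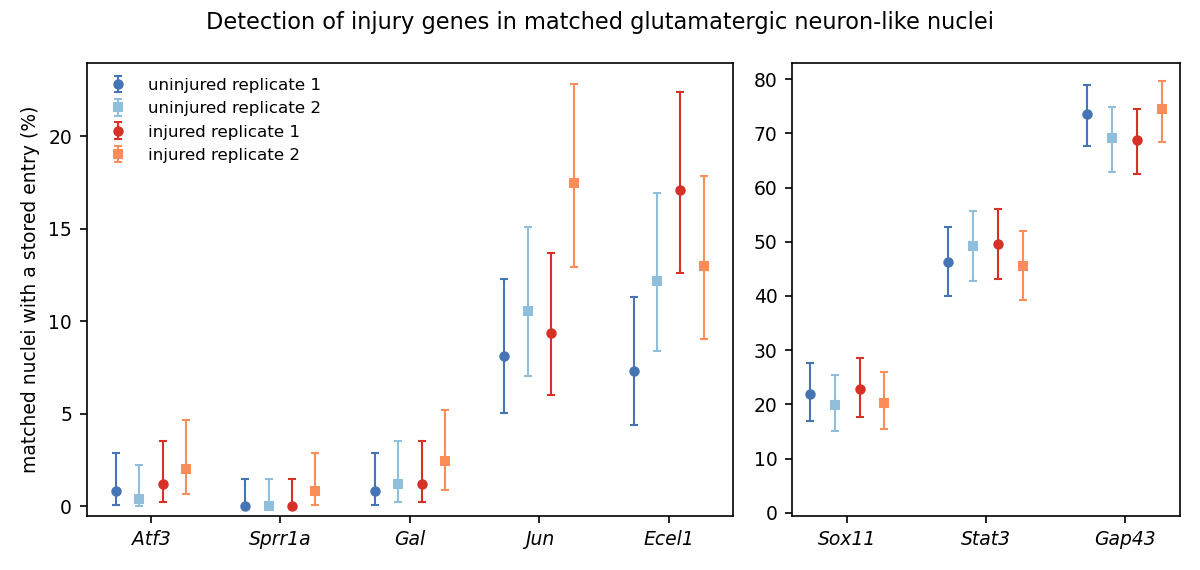
Share of matched glutamatergic neuron-like nuclei (y axis, percent) with a stored entry of each injury-response gene (x axis), each point 1 library of 246 matched nuclei of 1 draw with its exact 95% interval; the panels have different scales. Ecel1 is at 7.32% and 12.2% in uninjured and 17.1% and 13.0% in injured libraries, and Gap43 is between 68.7% and 74.4% in all 4.

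The fourth question was whether the response differed among groups of V2a-lineage neurons, since the series is titled for its diversity. The glutamatergic clusters 0, 1, 4, 8, 9 and 10 had at least 20 nuclei in every library, and cluster 6, with 14 nuclei in injured library 2, and cluster 13, with 16 in injured library 1, were not tested. Within clusters, edgeR called 0 of 32112 tests, with 802 at an unadjusted p under 0.05. DESeq2 called 34, of which 25 higher and 5 lower genes were in cluster 0, 2 and 1 in cluster 1, and 1 higher gene in cluster 8. The edgeR count was 872 without uninjured library 1, 131 without uninjured library 2 and 0 without either injured library.

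In the test of the difference itself, edgeR found 104 differences in 91 genes between the injury contrast of a cluster and that of the other glutamatergic nuclei, 74 positive and 30 negative. Stored shares of single clusters are given without matching on depth. In cluster 10, Reln, the secreted glycoprotein reelin, had an interaction log2 of 2.35 (SE 0.50, adjusted p 0.0118 in edgeR). Its level there was 28.4 and 32.3 CPM in uninjured and 68.5 and 243 CPM in injured libraries, and it was stored in 22.9%, 20%, 55.6% and 35.3% of the nuclei (uninjured 1, uninjured 2, injured 1, injured 2). Gpc5, a glypican and the other call of cluster 10, had an interaction log2 of −3.29 (SE 0.65), and was stored in 40%, 63.3%, 18.5% and 23.5%. Gpc5 there stood at 36.5 and 258 CPM in uninjured and 25.7 and 0 CPM in injured libraries. In cluster 4, led by Col8a1, Npsr1 and Nfib, Cdh20, a cadherin, had an interaction log2 of −1.78 (SE 0.40) and was stored in 45.8%, 28.4%, 19.05% and 13.5%. Sv2c, a synaptic vesicle glycoprotein, had an interaction log2 of −5.26 in cluster 8 (SE 0.87) and was stored in 55.0%, 54.8%, 42.9% and 33.3%, and Airn there had −2.36 (SE 0.44) and was stored in 75%, 73.8%, 51.4% and 42.9%. Erbb4, positive in cluster 4 (1.52) and chosen there after its value was seen, was stored in 52.5%, 50%, 57.1% and 32.4% there and in 37.9%, 44.9%, 23.4% and 17.4% in cluster 0, and the difference from the other glutamatergic nuclei in stored entries was 0.872 on the log2 scale. In cluster 4 Erbb4 stood at 55.1 and 165 CPM in uninjured and 227 and 18.7 CPM in injured libraries. The injured libraries thus lay on either side of the uninjured ones there. In the other glutamatergic nuclei it stood at 553 and 548 CPM in uninjured and 190 and 250 CPM in injured libraries.

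Of the 75 calls with detection below saturation, stored entries lay in the direction of the call in 62. In some of the other calls detection did not follow the counts. In cluster 8, which held 57 of the calls, Kcnip4, a potassium channel interacting protein, was at 4.54 and 0 CPM in uninjured and 265 and 771 CPM in injured libraries, yet was stored in 50%, 64.3%, 42.9% and 38.1% of the nuclei. Zfhx3 in cluster 8 was at 0 CPM in 3 of 4 libraries and at 196 CPM in injured library 1, and was stored in 65.0%, 59.5%, 57.1% and 57.1%. Fndc3a in cluster 1 (interaction log2 1.90, SE 0.20) was stored in 86.3%, 83.5%, 70.9% and 81.2%. Cluster 4 had 24 calls, among them Gpc5, Etl4 and Zfhx3 with positive and Rnf220 and Vsnl1 with negative interactions, and Gpc5 was stored there in 49.1%, 55.4%, 52.4% and 43.2%. Cluster 9 had 19 calls, led by Kirrel3, Kcnq5 and Trpm3 among positive ones and with Cpe negative. Unc5d and Lrp1b were among the other calls of cluster 8. The count was 99 to 326 when 1 library was left out, 326 without uninjured library 1, where most calls were in clusters 0 (172) and 1 (102) and cluster 8 had 24, and 0 when stored entries replaced counts in edgeR (2091 tests at an unadjusted p under 0.05).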

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

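All of the tests that weigh the clusters here were chosen only after their results were seen; the test of the difference between clusters was fixed before the data were examined.

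The injury contrast differed between glutamatergic clusters by the interaction test in 2 genes for cluster 1, 24 for cluster 4, 57 for cluster 8, 19 for cluster 9 and 2 for cluster 10, and in 0 genes for cluster 0 (edgeR, 2675 of 58029 tests at an unadjusted p under 0.05 over all clusters). The order of the clusters depended on the processing: without uninjured library 1 cluster 0 had 172 calls, cluster 1 102 and cluster 8 24, and without a low-count filter these had 60, 56 and 39. Over the 75 calls whose detection was not saturated, the median difference was 2.53 on the log2 scale from counts, and 0.410 in the direction of the call from stored entries, with a 75th percentile of 0.795. In stored entries 62 of the 75 lay in the direction of the call. With stored zeros read as emptied detections, stored entries include RNA free in the suspension, which can flatten a true difference between clusters. Of the 74 positive calls, 65 were in genes lower in the cluster than in the other clusters in uninjured libraries. Detection also compresses differences, so these values cannot tell the ambient subtraction from responses of the size the counts give. Of the 104 calls, 36 had a library at 0 counts in the cluster. The interaction test on stored entries, not matched on depth, called 0. These entries come from the same nuclei as the counts, so they are no independent evidence. Whether the clusters differ, and by how much, stays open. Among others this holds for Reln and Gpc5 in cluster 10, Cdh20 and Erbb4 in cluster 4 and Htr1f, the serotonin 1F receptor, in cluster 8.

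Htr1f in cluster 8, chosen after its values were seen, had an interaction log2 of −3.04 (SE 0.69) and was stored in 65% and 45.2% of the nuclei of the uninjured and 17.1% and 9.52% of those of the injured libraries.

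Cluster 7, neurons left unnamed and led by Snhg20, Nefl, Tubb3, Kifc2 and Ina, held 11.2% ± 0.889 of the injured and 2.71% ± 1.72 of the uninjured nuclei and entered the main comparisons between groups only as part of the share of unnamed neurons. Its nuclei had 0.332 of their library's median counts.

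Cluster 14, a non-neuronal cluster left unnamed and led by Inpp5d, Ly86, Dock8 and Siglech, held 2.63% ± 3.72 of the injured and 0.613% ± 0.362 of the uninjured nuclei, with 29 nuclei in injured library 1 and 0 of 389 in injured library 2, which allows up to 0.771%.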

How the results depend on the processing

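The tests on stored entries, on genes kept by retention, with unnamed neurons added and with the doublet calls of uninjured library 1 kept, and the interaction without single libraries, were chosen only after the data were seen. The causes were not tested unless stated. Tests of stored entries within and between clusters were not matched on depth. The 0 calls of edgeR in glutamatergic nuclei stayed 0 at a threshold of 0.1, with RLE scaling, limma-trend, nuclei of every class, doublets kept, doublets of uninjured library 1 kept, the same under another numerical kernel, equal nuclei and unnamed neurons added. They became 11 in DESeq2, 9 without a low-count filter (816 at an unadjusted p under 0.05), 2 and 7 among genes that kept a count in at least 25% and 50% of stored entries, and 849 with stored entries of all glutamatergic nuclei, whose depth differed between groups. Leaving out 1 library gave 0 to 359, the latter without uninjured library 1; the library left alone in its group is then assumed to vary like those of the other group.

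With stored entries of matched nuclei edgeR called 0 of 14102 genes (665 higher and 1089 lower at an unadjusted p under 0.05), RLE 0 (1701) and DESeq2 1 (451), leaving out 1 library gave 0 to 972 (972 without injured library 1, 348 without injured library 2), and 10 random draws gave 0 to 18 higher and 0 to 101 lower. Log2 fold changes from counts and from stored entries had r 0.443 across 10505 genes and 0.807 across 3227 genes that kept a count in at least 50% of stored entries; genes are not independent replicates.

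Calls within clusters became 34 in DESeq2 and 545 with stored entries, and 0 to 872 with 1 library left out (872 without uninjured library 1, 131 without uninjured library 2). Calls of a difference between clusters became 196 without a filter (60 in cluster 0, from 0, and 39 in cluster 8, from 57), 0 with stored entries and 99 to 326 with 1 library left out, 326 without uninjured library 1 (172 in cluster 0 and 24 in cluster 8). Lists called became 5 with stored entries of matched nuclei and 0 to 3 with 1 library left out: 1 without uninjured library 1 (cholesterol synthesis), and 3 without injured library 1, namely cholesterol synthesis, neuropeptides and caudal Hox genes. With an estimated correlation, run there after the data were seen, 0 lists were called without any 1 library. Class shares kept their direction in each alternative. Inhibitory nuclei stayed at 0 in both injured libraries with doublets kept, with those of uninjured library 1 kept and at resolution 1.0, but were 21 and 14 under another numerical kernel with doublets of uninjured library 1 kept, and 0 there at resolution 1.0.

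The replicate number as a block, which the labels do not tie to a shared day, gave 0 calls in glutamatergic nuclei (101 at an unadjusted p under 0.05), 80 with stored entries of matched nuclei, 2 in clusters (552) and 0 lists (7). Libraries with the same number did not deviate together (correlation across genes of −0.058 in counts and −0.024 in stored entries), so the numbers were not taken to pair the libraries.

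For log2 fold changes a reversal is a change of sign by more than the SE in both settings, and 109 of 114 named genes tested had none. By sign alone, 25 of the 99 genes with detection below saturation had opposite log2 fold changes in counts and in stored entries of matched nuclei, Nr4a1, Flrt3 and Pnn among them. Reversals with stored entries of matched nuclei were those of Leng9 (−0.17), Sv2b (0.27), Zfhx3 (0.0930) and Zfhx4 (0.10), and for Slc17a6 without injured library 2 (−7.27, against 4.67 without uninjured library 1). Injured minus uninjured shares are compared by sign alone, whatever their spread, and changed sign for Gap43 (−10.1 percentage points) and Sox11 (−7.215) with stored entries not thinned, and for Stat3 with stored entries matched (−0.203) and not thinned (−5.84). Depth limits the shares of nuclei with a count: thinning left out 26, 30, 116 and 40 shallower nuclei (uninjured 1, uninjured 2, injured 1, injured 2).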

Other observations

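All of the tests given here were chosen only after the result was seen, and the genes of the first paragraph were chosen after their values were seen.

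Several genes differed in detection across neuron classes, taken from stored entries without depth matching. Cd163l1 was stored in 64.5% and 43.2% of uninjured and 4.12% and 7.40% of injured glutamatergic nuclei, and was lower in both injured libraries than in both uninjured ones in all 8 glutamatergic clusters, as were Has1 and Fgf1, against 4 of 8 for Erbb4; Thsd4 was higher in both in 2 of 8. In unnamed neurons the same gene was stored in 30.8% and 27.9% against 1.49% and 2.38%. Has1 was stored in 50.6% and 54.5% of uninjured and 22.4% and 28.4% of injured glutamatergic nuclei, and in unnamed neurons in 26.9% and 28.7% against 5.97% and 4.76%. Fgf1 was stored in 86.3% and 80.9% against 57.2% and 61.2% of glutamatergic nuclei, but in unnamed neurons in 42.3% and 23.9% against 20.9% and 33.3%. It lies within Arhgap26 on the opposite strand, and its fall was not tested apart from that of the antisense genes described below. Thsd4 was stored in 57.0% and 56.3% against 62.7% and 64.2% of glutamatergic nuclei, and the other way in unnamed neurons, in 42.3% and 45.8% against 22.4% and 33.3%. Erbb4 was stored in 42.2% and 49.8% against 29.1% and 24.6% of glutamatergic nuclei and in 34.6% and 52.6% against 20.9% and 14.3% of unnamed neurons; it was also stored in 89.8% of the oligodendrocyte-like nuclei of uninjured library 2. Unnamed neurons are of different clusters in the libraries, with cluster 5 holding 179 of those of uninjured library 2 and cluster 7 65 and 41 of those of the injured libraries, and whether the classes differ was not tested. Pcsk1n, the gene of the neuroendocrine peptide precursor proSAAS, had 0 counts in every library but was stored in 64.3%, 63.0%, 75.3% and 97.0% of glutamatergic nuclei.

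In stored entries of matched glutamatergic nuclei, all 23 oxidative phosphorylation genes had positive log2 differences (median 0.40), and camera called the list (adjusted p 5.25e-05) but not with an estimated correlation (p 0.356, adjusted p 0.945), with 2 members higher adjusted over the list alone and 0 over all genes. Camera also called neuropeptides (8 of 8 positive, median 0.30, 1 member higher adjusted over the list alone), caudal Hox genes (8 of 8, median 0.32, 0 members), the axon growth cytoskeleton (18 of 22, 4 members) and synaptic vesicle genes (20 of 22, 0 members), each at adjusted p 0.0439. The estimated-correlation p of camera was 0.101 for neuropeptides, 0.342 for caudal Hox genes, 0.218 for the cytoskeleton and 0.168 for vesicle genes (adjusted p 0.945 for each), and the adjusted p of fry was 0.548 for all 5 lists. The list tests on stored entries were not run with a library left out, so whether these rises rest on 1 library is not known. The injured tissue lacked segments C1 and C2. Without passing, the stress response list had 9 of 11 members positive (adjusted p 0.0628), the p53 and apoptosis list 9 of 10 (0.106) and the mitochondrially encoded genes 4 of 10 (0.822). Adjusted over the list alone, 1 stress response, 2 sodium channel and 2 heat shock genes were higher, and 2 serotonin and monoamine receptor genes and 1 perineuronal net gene lower.

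In counts, 88 genes were at 0 in both uninjured libraries and above the floor in both injured ones, and 103 the reverse. A rise in glutamatergic neurons after injury and the ambient subtraction were weighed for the 88. Their log2 difference in detection in matched nuclei had a median of 0.173 and a 75th percentile of 0.383. In counts the lower bound of the log2 difference had a median of 4.3, so detection rose far less than the counts. For the 103 the median was −1.50, so detection followed the counts there and the weighing below does not extend to them. The uninjured libraries were also the deeper ones, by at least 1.27 times in median counts per glutamatergic nucleus, which argues against shallow sequencing as the source of the zeros. The subtraction and a rise were both judged by the detection difference alone. By the way the 88 were chosen, any stored entry of theirs in the uninjured libraries held a 0. RNA free in the suspension can also flatten detection. The values therefore cannot tell the subtraction from a rise, and both stay open.

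In matched nuclei, 609 genes that lie antisense to an abundant neuron gene were detected less often in the injured libraries: 92.1% had a negative log2 difference (median −0.64), against 46.0% of 9363 other genes stored in under 50% of nuclei (median 0.03), and their 504 hosts had a median log2 fold change of 0.02 in counts. The host median is from counts and not from stored entries of matched nuclei, so the measures are unlike. It does not show whether detection of the hosts changed. The 609 antisense genes gave 133 and 149 detections per matched glutamatergic nucleus in uninjured and 91.2 and 95.8 in injured libraries. The gap to other genes was −0.667 after matching on stored genes, which argues against depth in detected genes, although counts per matched nucleus stayed lower in the injured libraries. In the unnamed neurons of cluster 7, not matched on depth, these genes made up 6.09% and 6.17% of stored entries in uninjured and 3.29% and 3.82% in injured libraries, a log2 ratio of −0.786 (bootstrap interval −0.877 to −0.701 over genes, which are not independent). Median stored genes there were 3562 and 2346 in uninjured and 1584 and 2365 in injured libraries, on 22, 31, 65 and 41 nuclei. Matching gave a log2 ratio of −0.743 but left only 2 nuclei per library, so the comparison at similar depth is that of the 2 libraries with medians of 2346 and 2365, at 6.17% and 3.82%. This argues against a fall in the glutamatergic clusters alone, although cluster 7 may hold V2a-lineage neurons too. Fewer antisense reads in the injured libraries may account for it, and injury, segment range and library handling go together with the group and remain open.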
